A study of Mus musculus with 6 samples.

How the data were processed

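Poly-A RNA was sequenced from whole kidneys of wild-type mice 28 days after 20 min (3 samples) or 35 min (3 samples) of ischaemia. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase, and made into libraries with the NEBNext Ultra RNA kit after poly-T selection, with random-hexamer priming. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and the mouse build mm10. The roles of these tools, the counting mode, the strand setting and the annotation release are not given in the sources used here. The table deposited by the authors holds raw read counts per Ensembl gene, whole numbers with a different total in each library. Reads that fall on a gene and on an antisense or overlapping gene cannot be told apart where strand is unknown, and genes with near-identical copies are uncertain.

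Column names gave the group of each library by its minutes of ischaemia, and their numbers matched no sample title, so each column was used as a replicate of its group with no pairing. No column of per-sample values was left out. Gene counts summed to 15366602, 17730967 and 15433713 in mild libraries 7, 8 and 9 and to 17679697, 15240491 and 15589500 in severe libraries 13, 14 and 15. A gene with 0 counts could have up to 3 counts, which is 0.169 to 0.207 CPM, and this floor and the counting interval printed for 1 gene cover counting error only. Replicate pairs differed by 3.83 to 5.59 times the sampling noise among mild and 15.3 to 77.1 times among severe libraries (chi-square per degree of freedom), so none was a repeated library.

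Genes were filtered with filterByExpr of edgeR 4.0.16, scaled by TMM and tested with the quasi-likelihood F test with robust dispersion (R 4.3.3), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. TMM factors lay between 0.943 and 0.945 in mild libraries and were 0.974, 1.17 and 1.04 in severe libraries 13, 14 and 15. CPM values use these factors. Standard errors of log2 fold changes are the fold change divided by the root of F. The biological coefficient of variation was 0.144.

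The 44 gene lists were fixed before the data were examined, and 1025 of their 1028 members matched a gene in the table, through older symbols where needed (Emr1 for Adgre1). Lists with at least 5 tested members, 40 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The same test with an estimated correlation and fry were run beside it. Counts per list are given with p-values adjusted over the list alone and over all genes tested. Macrophage scores were compared by exact permutation over the 20 assignments of the 6 libraries. Principal components used the 500 most variable genes.

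Genes were named by a rule fixed before the data were examined. It takes 20 anchor genes, up to 8 genes per direction past the threshold with the largest change, the up to 4 members of each described list with the smallest p, and, since fewer than 10 genes passed, the 10 with the smallest p. Genes outside that rule are marked where they appear.

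The alternatives set beforehand were RLE, upper-quartile and library-total scaling, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, non-robust dispersion, a fold threshold of 1.5, the removal of mitochondrial genes and genes over 1% of counts, each library left out in turn, and other prior counts and summaries for lists and scores. A threshold of 0.10, a variance per group in limma-voom, an offset for GC content and gene length, and camera on quality-weighted values were added after seeing the data.

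The pipeline was tested on simulated counts for 14760 genes with the means and depths of these libraries. It recovered 35.4% of genes changed 1.5-fold, 71.2% of those changed 2-fold and 93.9% of those changed 4-fold. Of 149 genes called there, 17 were false, a share above the threshold of 0.05. A shifted list was found and 0 other lists were called. Genes were drawn independently there, with the same dispersion in both groups. In the real data the matrix list had an estimated correlation of 0.863, and severe kidneys varied more than mild ones. The simulation therefore cannot show how the list test behaves with correlated genes, or how many genes are recovered with unequal spread. For GC content, the longest transcript of GENCODE M21 was read with Biostrings for 99.6% of tested genes. Of 35275 gene IDs, 34490 are in that annotation, and 72.3% of those have the same start and end there, Slco2b1 among them and Trib2 not; printed coordinates are those of the table. Figures were drawn with matplotlib.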

Results

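Gene expression was measured by poly-A RNA sequencing in 6 kidneys of wild-type C57BL/6 mice, taken 28 days after ischaemia-reperfusion injury, in which renal blood flow is stopped and then restored. In 3 kidneys ischaemia had lasted 20 min (mild injury) and in 3 it had lasted 35 min (severe injury). Uninjured kidneys were not analysed here, so every difference is between the longer and the shorter ischaemia. The libraries held between 15240491 and 17730967 gene counts, and 14883 of 35275 genes had enough counts for a test. The libraries carry the numbers 7, 8 and 9 (mild) and 13, 14 and 15 (severe). The labels do not say that the kidneys came from separate mice, so the p-values measure only the spread between these samples. The comparison asks how far the longer ischaemia leaves more fibrosis and another macrophage state at the time of the transition from acute injury to chronic disease.

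Severe kidneys had higher levels of genes for extracellular matrix, fibroblasts, macrophages and injured tubule, and lower levels of genes for tubule transport and mitochondrial metabolism, by a list test with a preset correlation. With an estimated correlation 0 lists passed (lowest camera adjusted p = 0.464), with fry 0 (lowest adjusted p = 0.0887), and 0 members of these lists passed over all genes tested. Slco2b1, an organic anion transporter, rose from 16.6 ± 0.791 to 36.7 ± 0.538 CPM (read counts scaled to the TMM-adjusted library size; mean ± SD, n = 3 each), a log2 fold change of 1.15 ± 0.08 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00814). Trib2, a pseudokinase of the tribbles family, fell from 118 ± 13.04 to 56.8 ± 0.362 CPM, a log2 fold change of -1.05 ± 0.10 (edgeR, adjusted p = 0.0367). Slco2b1 (ENSMUSG00000030737) lies on the minus strand of chromosome 7 from 99657804 to 99711340, and Trib2 (ENSMUSG00000020601) on the minus strand of chromosome 12 from 15791727 to 15816877, in mm10 coordinates.

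These 2 were the genes with an adjusted p under 0.05 among the 14883 tested. The next 8 by p-value did not pass (adjusted p from 0.0596 to 0.0867) and are given as values. The insulin receptor substrate Irs2 had a log2 fold change of -1.14 ± 0.12 (adjusted p = 0.0596). Clca1 stood at 2.24 ± 0.26 and the macrophage elastase Mmp12 at 2.38 ± 0.28. Mfge8, a bridging protein for the uptake of dying cells, stood at 0.63 ± 0.07. The myeloid receptor Gp49a stood at 1.76 ± 0.21, the potassium channel Kcnn4 at 1.72 ± 0.23, the lysosomal glycoprotein Cd68 at 1.27 ± 0.17 and Osgin1 at -0.80 ± 0.11. At an unadjusted p under 0.05 there were 2352 genes higher and 1175 lower in severe kidneys. All 3 severe libraries lay outside the range of the mild libraries for 2658 genes on the higher side and 2398 on the lower side, together 34.0% of tested genes. By chance 10% is the mean over all assignments of the libraries. Genes are not independent, so the share in any single assignment can lie far from that mean.

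Severe kidneys varied more than mild ones: 73.0% of genes had the larger SD there, and the median SD on the log2 scale was 0.193 against 0.103 in mild kidneys. Without severe library 13 the count of genes past the threshold was 3269, and without severe library 14 it was 501. Without severe library 15 it was 1, and without mild library 7, 8 or 9 it was 0, with 2196, 2137 and 2345 genes at an unadjusted p under 0.05 (edgeR). Slco2b1 and Trib2 stayed past the threshold without library 13 or 14. Neither did without library 15 or any 1 mild library, where the adjusted p lay between 0.0546 and 0.0996 for Slco2b1 and between 0.0881 and 0.251 for Trib2. Trib2 also missed it with library totals as the scaling (adjusted p = 0.0944), and both missed it against a fold threshold of 1.5 (0.159 and 0.391). The full data gave 1092 genes with DESeq2 and 2 with limma-voom.

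**Figure D1:**
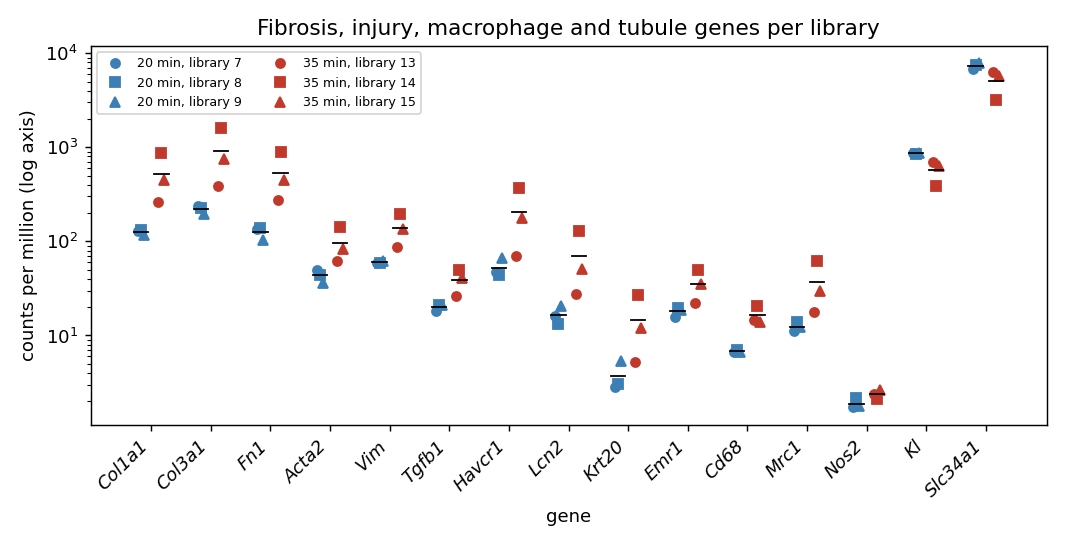
CPM (log axis) of 15 of the 20 anchor genes fixed before the data were examined, in the 3 kidneys after 20 min (blue) and the 3 after 35 min of ischaemia (red). Each point is 1 library, shapes tell libraries apart within a group, and black lines are group means. The anchors not drawn are Arg1, Cd163, Tnf, Il1b and Ccl2, and all of these but Arg1 overlapped between the groups. Col1a1 ranged from 116 to 132 CPM in mild and from 265 to 860 CPM in severe libraries, with severe library 14 highest, while Nos2 overlapped between the groups.

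Matrix genes stood higher in severe kidneys as a group. All 35 measured genes of the extracellular matrix list were higher in every severe library than in every mild library, and 35 passed adjusted over the list alone, against 0 over all genes tested. The fibrillar collagen gene Col1a1 went from 125 ± 8.29 to 523 ± 305 CPM (log2 fold change 2.06 ± 0.38, SE, n = 3) and Col3a1 from 219 ± 23.6 to 911 ± 616 CPM, a log2 fold change of 2.06 that was 1.38 without severe library 14. Fibronectin (Fn1) stood at a log2 fold change of 2.10 ± 0.39, the small proteoglycan Bgn at 1.52 ± 0.27 and elastin (Eln) at 1.13 ± 0.18. The median over the list was 1.62, and the list passed against all other genes (camera adjusted p = 9.29e-17; adjusted p = 0.464 with an estimated correlation).

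Of 28 tested matrix-remodelling enzymes, 23 were higher adjusted over the list alone and 0 over all genes. They included Mmp12 (3.79 ± 0.555 against 19.8 ± 6.51 CPM), the collagen cross-linking enzyme Lox (7.27 ± 0.918 against 44.98 ± 31.0 CPM) and Loxl1 at a log2 fold change of 1.40 ± 0.25. Lox had a log2 fold change of 2.63, and of 1.91 without severe library 14. The list had a median log2 fold change of 1.52 (camera adjusted p = 6.57e-09; adjusted p = 0.464 with an estimated correlation). Among 24 fibroblast, pericyte and myofibroblast markers, 19 were higher adjusted over the list alone and 0 over all genes, with a median of 1.05 (camera adjusted p = 4.5e-09; adjusted p = 0.464 with an estimated correlation). Dkk3 stood at a log2 fold change of 1.41 ± 0.23, the intermediate filament gene desmin (Des) at 0.998 ± 0.162 and the mesenchymal receptor Pdgfrb at 1.32 ± 0.25. Smooth muscle actin (Acta2), which marks myofibroblasts, stood at 1.14 ± 0.28 and vimentin (Vim) at 1.21 ± 0.25. Of 32 genes of TGF-beta, Wnt and hedgehog signalling, 13 were higher and 1 lower adjusted over the list alone, 0 over all genes (median 0.38, camera adjusted p = 0.00138; adjusted p = 0.475 with an estimated correlation). The lower one was the integrin subunit Itgb6 at -0.25 ± 0.09, chosen after its values were seen. Tgfb1 stood at 0.95 ± 0.21, Tgfb3 at 1.45 ± 0.25 and Tgfbi, a matrix protein induced by TGF-beta, at 1.32 ± 0.20.

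All 25 general macrophage and monocyte markers were higher in severe kidneys adjusted over the list alone, and 0 over all genes. Lysozyme (Lyz2) went from 103 ± 15.3 to 343 ± 145 CPM and Cd68 from 6.83 ± 0.214 to 16.5 ± 3.67 CPM (n = 3 each). The F4/80 gene, listed as Emr1, stood at a log2 fold change of 0.98 ± 0.26. The list had a median of 1.12 (camera adjusted p = 3.11e-13; adjusted p = 0.464 with an estimated correlation). In the same libraries the endothelial list had a median of 0.12 and the podocyte list one of -0.04.

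Genes associated with the M2 state, the alternatively activated form linked to repair, included 14 of 18 tested members that were higher adjusted over the list alone and 0 over all genes. Their median log2 fold change was 1.29 (camera adjusted p = 1.25e-07; adjusted p = 0.464 with an estimated correlation). The arginase gene Arg1 had 3 counts over the mild libraries and 147 over the severe ones, a ratio of 43.8 with a 95% counting interval from 14.7 to 215. It stood at 2.09, 5.46 and 0.861 CPM in severe libraries 13, 14 and 15, and its fitted log2 fold change of 5.27 was 4.35 without severe library 14 and 6.07 without mild library 8. The mannose receptor Mrc1 stood at 1.56 ± 0.41, Clec7a at 1.64 ± 0.28, the interleukin-1 antagonist Il1rn at 2.14 ± 0.47 and the scavenger receptor Cd163 at 1.03 ± 0.40, the last with overlapping groups. Without severe library 14 Mrc1 stood at 0.93 and Il1rn at 1.55. Of 14 tested members of the M1 list, the classically activated form, 2 were higher adjusted over the list alone (Socs3 at 1.66 ± 0.39 and Cd38 at 0.56 ± 0.15) and 0 over all genes. The inducible nitric oxide synthase Nos2 stood at 1.89 ± 0.234 CPM in mild and 2.39 ± 0.253 CPM in severe kidneys. Tnf stood at a log2 fold change of 0.74 ± 0.47 and Il1b at 0.79 ± 0.32, with overlapping groups for both. The M1 list still passed against all other genes with a median of 0.73 (camera adjusted p = 0.000272; adjusted p = 0.464 with an estimated correlation). Its mean log2 CPM, set against the mild mean, overlapped between the groups. It was 0.09, 1.12 and 0.80 in severe libraries 13, 14 and 15 and 0.23 in mild library 9.

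Of 20 genes of scar-associated macrophages, 10 were higher adjusted over the list alone and 0 over all genes, with a median of 0.46 (camera adjusted p = 0.00138; adjusted p = 0.464 with an estimated correlation). Gpnmb went from 1.02 ± 0.607 to 13.4 ± 11.3 CPM (log2 fold change 3.68, 2.74 without severe library 13 and 4.28 without mild library 8) and the lipid receptor Trem2 from 1.88 ± 0.169 to 7.33 ± 3.94 CPM. To set state against number of macrophages, the mean log2 CPM of each state list was taken minus that of the general macrophage list. In whole-kidney RNA other cells can also express members of the state lists, and the scar-associated and collecting duct lists share a member. Such a score therefore cannot part a change of macrophage state from a change in other cells. This score differed between severe and mild kidneys by -0.39 for M1 (exact permutation test, two-sided, p = 0.1), 0.12 for M2 (exact p = 0.3) and -0.42 for the scar-associated list (exact p = 0.2). M2 minus M1 differed by 0.51 (exact p = 0.1); it was higher in each severe library than in each mild library, but not when only members with a mean log2 CPM of at least 1 were kept (0.27, exact p = 0.2) or with medians over members (0.55, exact p = 0.3). With 3 against 3 kidneys 0.1 is the smallest p such a test allows, and after adjustment over the 4 scores p lay between 0.2 and 0.3. The M2 score turned to -0.11 with that minimum and to -0.0219 with medians, and was 0.21 with a prior count of 0.5 and 0.06 without severe library 14. The scar-associated score was -0.26 without severe library 14 and -0.72 with medians.

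**Figure D2:**
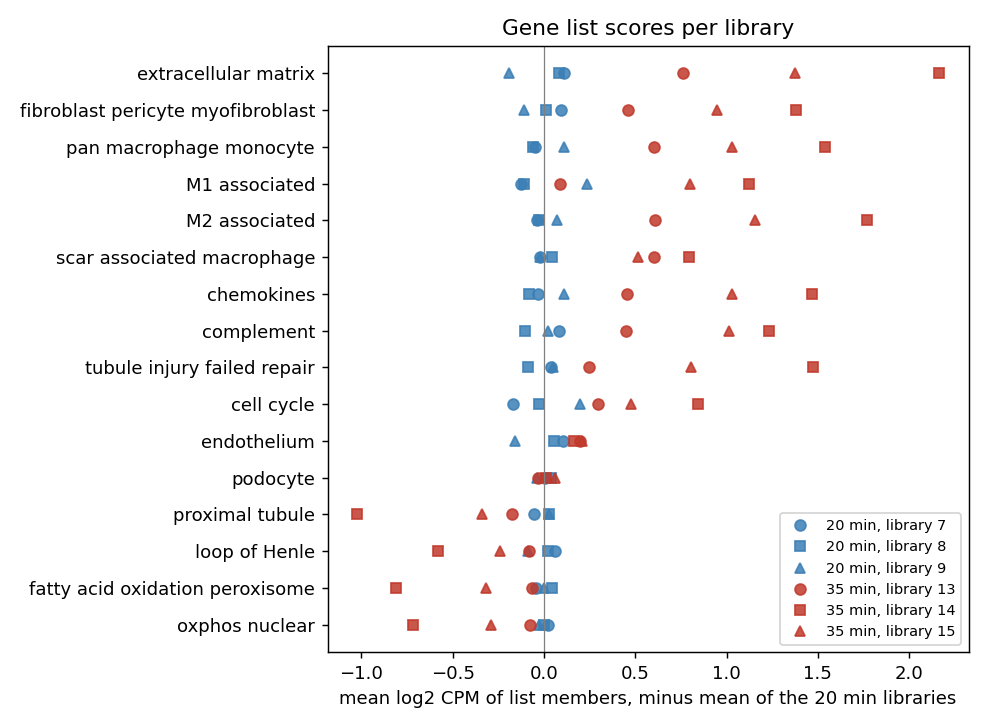
Scores of 16 of the fixed gene lists in each library, as the mean log2 CPM of the members minus the mean of the 3 libraries after 20 min (x axis, log2 units); blue points are mild and red points severe libraries, 1 point per library. The matrix list stood at 0.76, 2.17 and 1.37 in severe libraries 13, 14 and 15 and between -0.19 and 0.11 in mild libraries, while the podocyte list stayed between -0.04 and 0.06.

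Further immune lists were higher in severe kidneys. Of 17 genes of dendritic cells and antigen presentation, 13 were higher adjusted over the list alone and 0 over all genes, among them Flt3 at a log2 fold change of 1.08 ± 0.23, Irf8 at 0.65 ± 0.14 and H2-DMa at 1.004 ± 0.233. Of 21 chemokine genes 15 were higher adjusted over the list alone and 0 over all genes, with Ccl9 at 1.90 ± 0.32 and Cxcl14 at 1.53 ± 0.28. The monocyte attractant Ccl2 stood at 1.30 ± 0.54 with overlapping groups, and at 0.60 without severe library 14. Of 19 complement genes 13 were higher adjusted over the list alone and 0 over all genes, with C7 at 1.74 ± 0.28 and C1s1 at 1.68 ± 0.28. The interferon list had 9 of 32 and the NF-kappa-B list 12 of 16 genes higher adjusted over the list alone, 0 over all genes, with Oasl2 at 0.74 ± 0.17 and Tnfrsf1b at 1.36 ± 0.26. These 5 lists had camera adjusted p-values of 5.17e-08, 1.07e-06, 0.000206, 5.13e-07 and 6.79e-06 in that order, and each had adjusted p = 0.464 with an estimated correlation. The T and NK cell list had a median of 0.61 with 0 of 18 members passing (camera adjusted p = 0.00397; adjusted p = 0.517 with an estimated correlation), and its call ended without mild library 7 (median 0.28) and with library totals as the scaling (median 0.78). The score of the T and NK cell list also overlapped between the groups, with 0.13, 0.72 and 0.71 in severe libraries 13, 14 and 15. Mild libraries lay between -0.46 and 0.54. Il7r stood at 1.61 ± 0.41. B and plasma cell genes had a median of 0.19 (camera adjusted p = 0.283), with 4 of 13 higher adjusted over the list alone, 0 over all genes. These were Sdc1 at 0.82 ± 0.18, Ighm at 0.75 ± 0.17, Spib at 1.13 ± 0.33 and Cd22 at 1.61 ± 0.49.

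Markers of injured and incompletely repaired tubule were higher in severe kidneys, 22 of 30 adjusted over the list alone and 0 over all genes. The median was 0.97 (camera adjusted p = 1.3e-07; adjusted p = 0.464 with an estimated correlation). The injury marker Havcr1, which encodes KIM-1, went from 52.4 ± 12.1 to 206 ± 153 CPM. Lcn2, which encodes NGAL, went from 16.6 ± 3.71 to 69.2 ± 53.6 CPM. The retinoic acid enzyme Aldh1a2 stood at a log2 fold change of 2.36 ± 0.49, S100a6 at 1.45 ± 0.32 and Krt20 at 1.98 ± 0.57, the last with overlapping groups. Without severe library 14 the log2 fold change went from 1.98 to 1.23 for Havcr1, from 2.07 to 1.24 for Lcn2, from 2.36 to 1.64 for Aldh1a2 and from 1.98 to 1.20 for Krt20.

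Genes of every tubule segment tested were lower in severe kidneys as lists, with few single genes passing. Each list score was lowest in severe library 14, with -0.58 for the loop of Henle and -0.51 for the collecting duct. In severe library 13 the loop of Henle score was -0.0822, within the mild range (mild library 9 at -0.0860). The collecting duct score there was -0.0204, close to -0.0182 in mild library 9. The proximal tubule list had a median of -0.48, and 34 of its 46 genes were lower in every severe library than in every mild library, but 0 passed adjusted over the list alone or over all genes. Keg1 stood at 1453 ± 38.5 CPM in mild and 865 ± 179 CPM in severe kidneys, the phosphate transporter Slc34a3 at a log2 fold change of -0.71 ± 0.22, the glucose transporter Slc5a2 at -0.60 ± 0.21 and the phosphate transporter Slc34a1 at -0.53 ± 0.29. The loop of Henle had 2 of 22 genes lower adjusted over the list alone, the calcium-sensing receptor Casr at -0.51 ± 0.12 and the chloride channel subunit Bsnd at -0.64 ± 0.16, and 0 over all genes. The distal convoluted tubule had 1 of 18, the sodium-calcium exchanger Slc8a1 at -0.43 ± 0.08, and 0 over all genes. The collecting duct had 0 of 26, with the ammonia transporter Rhcg at -0.44 ± 0.15. Camera gave adjusted p-values of 3.95e-11, 0.00216, 0.000327 and 0.000353 for these 4 segments, and each had adjusted p = 0.464 with an estimated correlation. Klotho (Kl), a tubular co-receptor for FGF23, stood at 864 ± 8.17 CPM in mild and 569 ± 163 CPM in severe kidneys (log2 fold change -0.60 ± 0.22). The podocyte list did not pass (median -0.04, mean 0.02, camera adjusted p = 0.392), and 1 of its 24 members, Kirrel at 1.09 ± 0.22, was higher adjusted over the list alone, 0 over all genes. The endothelial list passed, with 3 of 27 members, Ramp2, Eng and Plat, higher adjusted over the list alone and 0 over all genes (median 0.12, camera adjusted p = 0.0356; adjusted p = 0.544 with an estimated correlation), and its call ended without mild library 9 (median 0.0477), severe library 13 (0.0815) or severe library 15 (0.114).

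Metabolic lists were lower in severe kidneys, with 0 members passing adjusted over the list alone and 0 over all genes in each. The median log2 fold change was -0.37 over 35 genes of fatty acid oxidation and peroxisomes, -0.34 over 45 nuclear genes of oxidative phosphorylation, -0.38 over 34 genes of the citric acid cycle, amino acid use and gluconeogenesis and -0.35 over 12 mitochondrially encoded genes. Camera gave adjusted p-values of 1.32e-08, 8.5e-11, 4.52e-08 and 0.000417, and each list had adjusted p = 0.464 with an estimated correlation. The list scores lay between -0.81 and -0.72 in severe library 14 and between -0.40 and -0.29 in severe library 15. In severe library 13 they were only -0.066, -0.074, -0.113 and -0.021 in the same order. The lowest mild scores were -0.045, -0.026, -0.055 and -0.014. The carnitine acyltransferase Crot stood at -0.57 ± 0.23, Acot12 at -0.50 ± 0.19, the complex I subunit Ndufb5 at -0.37 ± 0.13 and Prodh2 at -0.48 ± 0.14. Mitochondrially encoded genes took 10.4% to 10.7% of counts in mild libraries and 10.7%, 7.48% and 8.47% in severe libraries 13, 14 and 15. Glycolysis genes did not pass as a list (median -0.16, mean 0.11, camera adjusted p = 0.306), and 2 of 22, Eno2 at 1.42 ± 0.31 and Hk3 at 1.06 ± 0.26, were higher adjusted over the list alone, 0 over all genes.

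Proliferation and stress genes were higher in part. Of 35 cell cycle genes 21 were higher and 1 lower adjusted over the list alone and 0 over all genes (median 0.58, camera adjusted p = 1.32e-08; adjusted p = 0.464 with an estimated correlation). The spindle gene Nusap1 stood at 0.57 ± 0.14 and the mitotic kinase Aurkb at 1.02 ± 0.27. The lower one was the cyclin gene Ccnd1 at -0.38 ± 0.14, chosen after its values were seen. Of 25 senescence and p53 genes 7 were higher adjusted over the list alone and 0 over all genes (median 0.40, camera adjusted p = 0.000353; adjusted p = 0.464 with an estimated correlation). The cell cycle inhibitor Cdkn1a stood at 1.02 ± 0.21 and Phlda3 at 0.96 ± 0.21. Of 27 cell death genes 8 were higher adjusted over the list alone and 0 over all genes, with the necroptosis kinase Ripk3 at 1.18 ± 0.26 (median 0.23, camera adjusted p = 0.009; adjusted p = 0.464 with an estimated correlation). That list's call ended with library totals as the scaling (median 0.40). The oxidative stress list was lower (median -0.24, mean -0.06, camera adjusted p = 0.00112; adjusted p = 0.475 with an estimated correlation). Its score did not go one way, with 0.09 in severe library 13, above every mild library, and -0.26 and -0.15 in severe libraries 14 and 15 (exact permutation test, two-sided, p = 0.4). Its glutathione synthesis gene Gclc stood at -0.39 ± 0.13, while 2 of its 23 members, the NADPH oxidase subunit Cybb and the cystine transporter Slc7a11, were higher adjusted over the list alone and 0 over all genes.

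In all, camera with a preset correlation of 0.01 passed 19 lists as higher and 10 as lower of 40 tested. With the correlation estimated from the data 0 lists passed, with adjusted p-values from 0.464 to 0.986, and the fry test of a shared direction gave 0, with a lowest adjusted p of 0.0887.

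**Figure D3:**
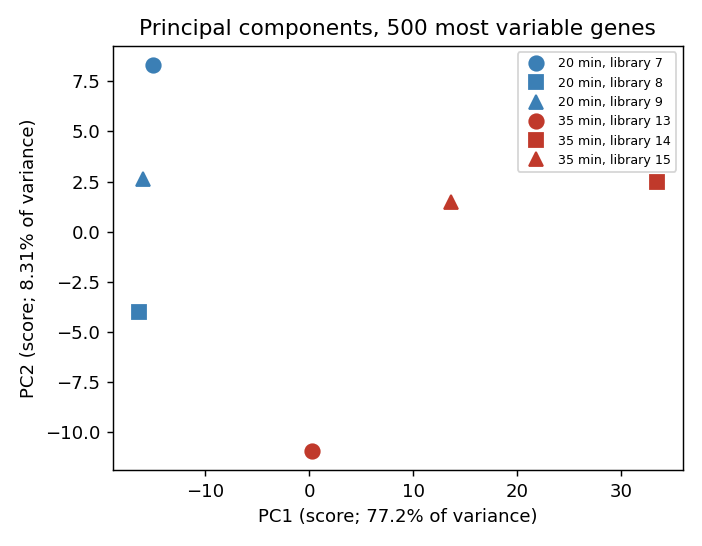
First and second principal components of the 500 most variable genes (scores without unit, with the percent of variance on the axes); blue points are mild and red points severe libraries, 1 point per library. The mild libraries lie between -16.4 and -15.0 on the first component, and severe libraries 13, 14 and 15 at 0.27, 33.4 and 13.7.

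The distances between libraries were larger among severe kidneys. The first principal component of the 500 most variable genes held 77.2% of the variance. Spearman correlations of log2 CPM across genes, which are not independent replicates, lay between 0.995 and 0.996 among mild libraries and between 0.973 and 0.992 among severe libraries. Severe library 14 had correlations of 0.959 to 0.961 with mild libraries, and severe library 13 had 0.992 to 0.993. The matrix, macrophage and injury lists were each highest in library 14 and lowest in library 13 among severe libraries, and the proximal tubule list ran the other way.

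**Figure D4:**
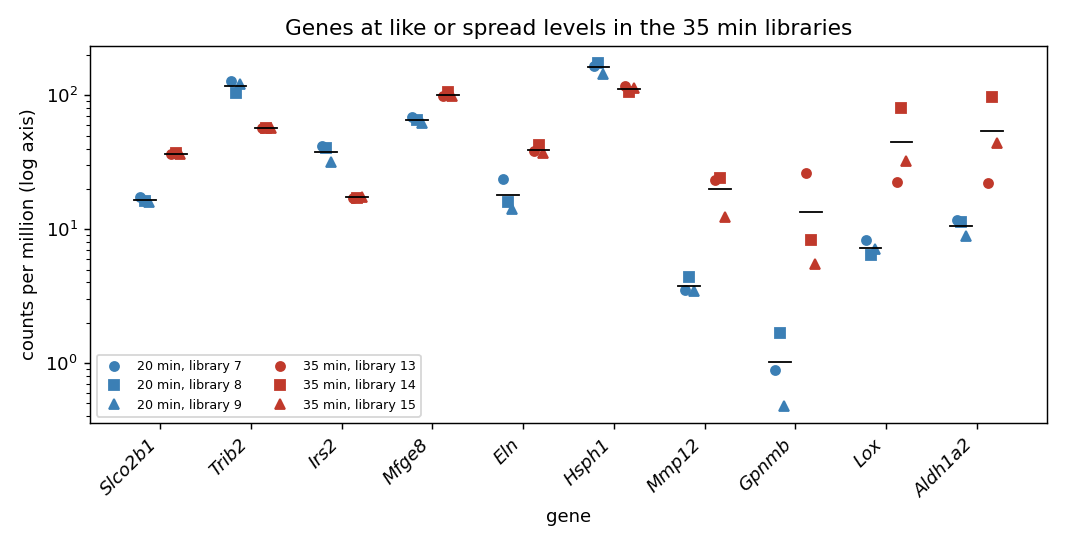
CPM (log axis) of 10 genes in the 3 kidneys after 20 min (blue) and the 3 after 35 min of ischaemia (red), chosen after their values were seen to show genes with little and with much spread among severe libraries; each point is 1 library and black lines are group means. Slco2b1 lay between 36.1 and 37.2 CPM in severe libraries, while Aldh1a2 lay between 22.0 and 97.1 CPM.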

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

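The count of genes past the threshold differed between settings, and the alternatives with an adjusted p under 0.10, a variance per group, an offset for GC content and length, and quality-weighted camera were chosen after seeing the data. Against 2 genes (1 higher, 1 lower), library totals alone gave 1 (higher), no filter 146 (134 higher, 12 lower), DESeq2 1092 (968 higher, 124 lower), limma-voom with sample quality weights 5041 (2706 higher, 2335 lower), a variance per group 225 (217 higher, 8 lower), an adjusted p under 0.10 616 (560 higher, 56 lower) and a fold threshold of 1.5 0, with 905 genes at an unadjusted p under 0.05; the cause was not tested. RLE and upper-quartile scaling, the stricter filter, non-robust dispersion, limma-voom and the removal of mitochondrial and most abundant genes gave 2, the same 2 genes, and the GC and length offset gave these and Irs2. Leaving out 1 library gave 0 to 3269 genes, with fewer samples in each fit; the 1 gene without severe library 15 was Mmp12. Library totals alone moved the median of all genes by 0.169 on the log2 scale, and changes under it are relative to that shift.

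Lists past the threshold numbered 29, and 0 with an estimated correlation and 0 with fry, which tests another question. They numbered 28 to 31 under the other settings, and 29 to 31 with 1 library left out. Of the 29, 27 kept their call and direction with library totals alone and 28 or 29 in each fit without 1 library. Among lists that did not pass, the direction of the test turned for endoplasmic reticulum stress (median 0.14 with library totals alone), female-biased genes (0.0269 without mild library 7, and 0.0235 to 0.754 over the fits without 1 library) and erythroid genes (0.85 with library totals alone, 0.0824 with the stricter filter, 0.0755 with quality weights, and -0.27 to 2.46 without 1 library, with 1.02 without mild library 9 and -0.27 without severe library 13); the cause was not tested.

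The M2 macrophage score minus the general score was 0.12 and turned to -0.11 with members of mean log2 CPM of at least 1 and to -0.0219 with medians; the cause was not tested. With 1 library left out it lay between 0.06 and 0.18, the M1 score between -0.47 and -0.32, the scar-associated score between -0.63 and -0.26 and M2 minus M1 between 0.42 and 0.58; the last was 0.27 with members of mean log2 CPM of at least 1. The first principal component held 67.6% of the variance over all tested genes. None of the 131 genes recomputed singly changed sign in the 19 alternative fits; of 2483 values 475 newly passed and 11 no longer did. The adjusted p lay between 1.54e-17 and 0.159 for Slco2b1 and between 6.85e-15 and 0.391 for Trib2 over these fits. Depth limits low genes such as Arg1, with 3 counts over the mild libraries.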

Other observations

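The tests on tubule share, the mislabelled library, the graded response, the time of day and quality-weighted lists were chosen after the values they rest on, or part of them, had been seen. In genes of heat shock and the immediate early response, members went both ways: the chaperone gene Hsph1 stood at 162 ± 14.9 CPM in mild and 111 ± 5.599 CPM in severe kidneys (log2 fold change -0.54 ± 0.10, SE, n = 3) and Dnajb1 at -0.42 ± 0.08, while the small heat shock gene Hspb1 stood at 1.21 ± 0.33 and Junb at 0.98 ± 0.25. Adjusted over the list alone 8 of 22 were higher and 2 lower, against 0 over all genes, and the list did not pass one way (camera adjusted p = 0.105), but did, as higher, without severe library 13 (median 0.75, camera adjusted p = 0.0181, preset correlation). With an estimated correlation and all libraries the camera adjusted p of this list was 0.602. The fry test for change in either direction passed 5 lists, this one among them, with the lowest adjusted p of 0.000631 for endoplasmic reticulum stress, a list with 0 of 22 members passing adjusted over the list alone, 0 over all genes, and with a median of -0.03 and a mean of 0.04. Male-biased, androgen-dependent kidney genes were lower as a list, with a median of -0.61 over 12 genes and 0 passing adjusted over the list alone or over all genes (camera adjusted p = 0.000204; adjusted p = 0.464 with an estimated correlation); Ugt2b38 stood at -0.59 ± 0.24. The mean of this list stood at -0.22, -1.58 and -0.41 in severe libraries 13, 14 and 15 against the mild mean, beside -0.18, -1.03 and -0.34 for the proximal tubule list.

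Beside the lists named above as not passing, those that did not pass with all libraries were female-biased kidney genes (median 0.35, camera adjusted p = 0.436), hypoxia genes (-0.17, 0.0702), endocrine genes (-0.03, 0.337), urothelium (0.31, 0.219), adipose tissue (-0.08, 0.365) and erythroid genes (0.72, 0.967). Of the female-biased genes Abcc3 and Slc7a12, 2 of 5, were higher adjusted over the list alone and 0 over all genes. Slc7a12 stood at 1.38, and at 0.62 without severe library 14. Hypoxia genes passed as lower without mild library 7 (median -0.14), mild library 9 (-0.16) or severe library 13 (-0.25), with library totals (-0.0149) and with quality weights (-0.20), at camera adjusted p-values from 0.0121 to 0.0478 with the preset correlation. With an estimated correlation and all libraries the camera adjusted p was 0.547. Urothelium passed as higher without mild library 7 (median 0.64, camera adjusted p = 0.000468) and with quality weights (0.78, 0.0258), also with the preset correlation. With an estimated correlation and all libraries it had a camera adjusted p of 0.629. The haemoglobin gene Hbb-bs, chosen after its values were seen, stood at 24.8 CPM in severe library 13 and at 0.824 to 5.15 CPM in the other libraries. Neutrophil genes had 4 tested members, mast cell and eosinophil genes 4, striated muscle 3 and adrenal 2, too few for a list test with all libraries. In most fits without 1 library more members were tested. The neutrophil list then had 5 to 7 and passed as higher without 7, 8, 9, 13 or 15 (median 1.63 to 1.88, camera adjusted p from 0.000426 to 0.00973). Without severe library 14 it stayed too small for a list test. The mast cell and eosinophil list had 5 and did not pass (camera adjusted p from 0.656 to 0.9). These fits used the preset correlation alone. Every list tested with an estimated correlation failed to pass. Adjusted over the list alone, 3 neutrophil genes (Mmp9 at 1.64 ± 0.34, Lcn2 and Csf3r) and 1 adrenal gene (Scarb1 at 0.35 ± 0.11) were higher, against 0 over all genes. Lcn2 is given above as an injury gene and Mmp9 is also in the matrix-remodelling list, so a higher neutrophil list need not mean more neutrophils. Of its members untested with all libraries, Ly6g, Mpo, Elane, Camp and Ngp had 0 or 1 counts in each group. S100a8 had 14 counts in mild and 44 in severe libraries, and S100a9 had 5 and 40. The adipose gene Adipoq, also chosen after its values were seen, stood at 0.0582, 0.0563 and 0.676 CPM in severe libraries 13, 14 and 15, and at 0 to 0.965 CPM in mild libraries. Matrix genes were highest in library 14. Gpnmb did not follow the order of the matrix genes, with 26.4, 8.27 and 5.53 CPM in severe libraries 13, 14 and 15.

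With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be had. The real split gave 2 genes and the highest other split 0, so 1 split gave as many. For lists the real split gave 29 and the highest other split also 29, with mild libraries 7 and 8 and severe library 13 against the rest, so 2 of the 10 splits gave as many. The remaining splits gave 28, 27, 24, 20, 18, 10, 7 and 3 lists. Camera with the preset correlation thus passed many lists in several mixed groupings too.

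Matrix, macrophage and injury lists stood higher and the proximal tubule list lower in severe libraries. A lower tubule share would raise every other cell type alike, yet the matrix list minus the mean of the podocyte and endothelial lists differed by 1.33 on the log2 scale, against an SD of 0.0791 in mild and 0.703 in severe libraries, which argues against it for matrix genes. For macrophage genes the same difference was 0.957, against SDs of 0.181 and 0.467, with every severe library above every mild one. The podocyte list differed by 0.0137. The bound was first the mild range of 0.317, which the macrophage gap of 0.314 missed. It was replaced by the SD of either group after these values were seen. The matrix gap of 0.623 was over its mild range of 0.147. For macrophage genes the values lean against an equal rise, but a bound changed in this way cannot decide it. Removing a trend on GC content and gene length left 2.05 of a matrix minus proximal tubule difference of 2.10, so such a bias does not account for this difference. The matrix list of severe library 13 stood 0.761 above the mild mean, with a gap of 0.652 against a mild range of 0.2995. Library 13 was thus unlike the mild libraries in matrix genes. That list parts the groups and was picked after its values were seen. With so few mild kidneys a more injured mild kidney under a severe label is not excluded. The length of ischaemia stays open as the biological explanation, as does a change in cell composition.

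The severe libraries differed among themselves in the genes that part them from mild ones. Across 14883 genes, which are not independent, severe library 14 minus 15 had a Spearman correlation of 0.374 with severe library 13 minus the mild mean, though these share no library; like differences between mild libraries gave at most 0.0201 in size. The correlation of 0.374 goes with a hypothesis of one graded response that the 3 severe kidneys reached to different degrees, library 14 farthest. The first principal component had already shown that order, so a positive value was likely beforehand and adds little to it. What sets the degree was not tested, and a difference in the injury or in handling stays open. So does one in the tissue that went into each extraction, though the samples are described as whole kidneys.

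Slco2b1, Trib2 and Irs2 stood apart from that gradient: Irs2 had 17.2, 17.2 and 17.5 CPM in severe libraries 13, 14 and 15 and 31.6 to 41.9 CPM in mild ones. Since insulin lowers Irs2, feeding before the kidneys were taken was tested. The prediction was higher sterol and lipogenic genes and lower fasting genes. Sterol and lipogenic genes had a median log2 fold change of -0.0666 over 13 genes (SD 0.267), with a highest value of 0.27, so they did not rise. Fasting genes had a median of -0.13 over 8 genes (SD 0.304), the direction feeding would give, with 3 of the 8 positive. Nothing measured here shows that whole kidney raises the first list on feeding, so the test cannot decide. The medians of lists of opposite clock phases (4 and 10 genes) differed by 0.159, but the shortfall from a shift of 0.5 was 0.341 and the members' spread 0.394; per library the difference of their means was 0.09, 0.36 and -0.29 in severe and 0.05, 0.18 and -0.23 in mild libraries, so the groups overlapped. The clock gene Per2, chosen after its values were seen, lay at 26.9 to 28.7 CPM in mild and 17.7 to 21.6 CPM in severe libraries. In the evening-phase list 2 of 10 genes were higher in severe kidneys, and in the morning-phase list 1 of 4. Most genes of both clock lists were thus lower, though the lists stand for opposite phases. With so few genes, feeding, another time of day and an effect of the longer ischaemia cannot be told apart. A test ranked by p also favours genes with little spread, and Slco2b1, Trib2 and Irs2 had the 3 smallest p-values. Irs2 had 295, 305 and 285 counts in severe libraries 13, 14 and 15. Counting error alone would spread such counts more than its CPM values differed, and the same held for Slco2b1 and Trib2. Levels this close therefore owe something to luck and to the ranking. A gap of over 0.3 and a severe range under 0.3 were seen in 68 of 13008 genes, 49 higher and 19 lower.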
